A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 36 samples.

How the data were processed

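RNA sequencing of 36 libraries of Synechococcus elongatus was analysed: wild type and a kaiABC knock-out, each after 1, 4 or 8 cycles of LD8:16 or LD16:8, with 3 libraries in each of 12 groups. Per the labels' protocols, cells grew on plates of BG-11 medium, with extra constant light before the cycles or a move to new plates during them, so that all had about 60 h of light by collection, 1 h before midday of their own photoperiod. RNA was preserved and extracted with commercial kits, treated with DNase and depleted of ribosomal RNA, per the labels' protocols. The time after lights on at collection (3 h in LD8:16 and 7 h in LD16:8) was worked out here from the lengths of the days. Nothing in the labels states that the replicates of a group were separate cultures, so the p-values measure the spread between libraries.

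The deposited values are counts in 1 table of 2781 rows and 36 columns. The submitters' processing notes name DESeq, Trim Galore 0.6.10, SAMtools 1.11.0, StringTie 2.1.7 and DESeq2 1.36.0, without the step each was used for in the form read here. The aligner, genome build, annotation version, strandedness and treatment of reads that map to several places are not given in the sources used here. All values were whole numbers of at least 0. The columns were joined to the samples by the code in each sample's description. The rows are 2712 whose IDs begin with gene, 55 whose IDs begin with rna and 14 assembled ones without a locus tag. The 2767 IDs with a locus tag were looked up in a reference table of 2785 genes, which uses tags of another form, and 0 matched. No gene names were therefore assigned, the 34 gene lists fixed before the counts were read had 0 matched members, and their tests were not run.

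Groups followed the sample titles. For 6 libraries titled 8 cycles of LD8:16 the treatment field gives LD16:8; the title was used because only the titles give 12 groups with replicates 1 to 3 in each. The plan, written before the counts were read, left ribosomal RNA rows out of library sizes and tests. Since the IDs do not show which of the 55 rna rows are ribosomal, all of them and the 14 assembled rows were left out. The rna rows held 7.25% to 15.4% and the assembled rows 1.1% to 4.07% of each library's counts.

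Totals over all rows were 63716800 to 122298000 counts per library (median 84245000), and over gene rows 55678900 to 108238000 (median 73607400). The 10 rows with the most counts held 23.2% to 38.2% of the gene-row counts of a library. Of the gene rows, 9 had 0 counts in every library and 95 in all fell below the filter. A count of 3 came to 0.0277 to 0.0539 CPM, which bounds what a count of 0 allows by counting error alone. No library was a copy of another: the lowest chi-square per degree of freedom between libraries of a group was 138. Correlations of log2 CPM within groups were 0.885 to 0.972 (median 0.957), and the highest between groups was 0.981.

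Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Rows passing filterByExpr by group (2617) were scaled by TMM (factors 0.799 to 1.07 in wild type and 0.916 to 1.23 in the knock-out). A model with a mean for each of the 12 groups was fitted to all 36 libraries, with robust quasi-likelihood dispersion, and contrasts were tested by edgeR's quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p below 0.05 was a call. The 16 contrasts were the photoperiod difference in each genotype at 1, 4 and 8 cycles, its difference between genotypes at each number of cycles, its change from 1 to 8 cycles in each genotype, 8 against 1 cycle in each genotype and photoperiod, and the genotype difference averaged over the 6 regimes. Contrasts of 8 with 4 cycles within each photoperiod and genotype, genotype differences within single regimes, and the row scores were added after the data were seen. Standard errors are those of the coefficient, with the quasi-likelihood dispersion. Levels are TMM-scaled CPM, averaged over libraries. A fold was not given for a row with at most 3 counts in every library of a compared group. Chance expectations for rows called in 2 contrasts are products of the call rates over tested rows. They take the 2 sets of calls as independent across rows. All contrasts of a fit share each row's dispersion estimate, so these expectations may be too low. Scores are means of log2 CPM (prior count 2), compared between 3 and 3 libraries by exact permutation and, for differences between genotypes, by 400 regroupings of genotype within photoperiod, whose null is no genotype difference in either photoperiod; the change between cycles in the knock-out was tested by regrouping cycles in the same way.

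Rows named in the text are at most 2 higher and 2 lower per contrast: those with the largest log2 difference among rows with an adjusted p below 0.05, a mean of at least 10 CPM and, for contrasts of 2 groups, no overlap between the groups. The planned rule also asked for a gene name or product, which could not be applied, and for more rows. Rows RS06230, RS06235 and RS06240 were left out of it and stand in the genotype check. Row RS02620 is the only call of its contrast.

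The procedure was tested on simulated counts with 200 changed rows, 100 at 2-fold and 100 at 4-fold. For the wild-type photoperiod contrast at 8 cycles (2613 rows) it recovered 57% and 87%, with 10 false among 154 calls. For genotype by photoperiod at 8 cycles (2610 rows) it recovered 35% and 84%, with 8 false of 127. For cycles by photoperiod in wild type (2612 rows) it recovered 23% and 79%, with 3 false of 105. For the averaged genotype contrast (2611 rows) it recovered 92% and 98%, with 6 false of 196.

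Alternatives planned before the data were examined were DESeq2 size factors in edgeR, no count filter, the DESeq2 1.42.0 Wald test, the replicate number as a block, the series of library codes as a covariate (the order of conditions repeats every 12 codes up to 36, and all later codes form the last series), rna and assembled rows kept, only the groups compared in the fit, 8 against 4 cycles in place of 8 against 1 cycle for cycles by photoperiod, the 6 libraries with disagreeing labels left out, and each library left out in turn. Alternatives chosen after the data were seen left out the 2 libraries that go against their genotype label, the 3 libraries coded 14 to 16, the 4 coded 14 to 17, or the 12 libraries of 1 cycle. Labels were also regrouped in up to 50 splits for each contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.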

Results

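RNA of the cyanobacterium Synechococcus elongatus, a photosynthetic bacterium with a circadian clock, was sequenced in 36 libraries. Of these, 18 were labelled wild type and 18 as a knock-out of kaiABC, the genes of the core clock oscillator. Cells on plates received 1, 4 or 8 daily cycles of short days (LD8:16, 8 h of light and 16 h of dark) or long days (LD16:8), which gave 12 groups of 3 libraries. All cells were collected 1 h before midday, which by the lengths of the days lay 3 h after lights on in LD8:16 and 7 h after lights on in LD16:8. A photoperiod difference below is therefore also a difference in hours after lights on. Per the labels' protocols, extra constant light before the cycles or a move to new plates brought all cells to about 60 h of light. These steps can differ with photoperiod and with the number of cycles, and their part cannot be told apart from either. The deposited counts came to 63716800 to 122298000 per library (median 84245000), of which 55678900 to 108238000 (median 73607400) lay in the 2712 gene rows used here. A count of 3, the upper limit that a count of 0 allows, was 0.0277 to 0.0539 CPM (counts scaled by library size, as usually given). For 6 libraries the title gave 8 cycles of LD8:16 and a treatment field gave LD16:8. They are grouped here by title, and every comparison of LD8:16 at 8 cycles rests on that choice.

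Rows are named by the part of their ID after gene-SYNPCC7942_, since the files do not pair these IDs with gene names. Photoperiod differences are LD8:16 minus LD16:8 and genotype differences are knock-out minus wild type, both in log2 units. Calls are gene rows with an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

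The genotype labels were compared with 3 consecutive rows, RS06230, RS06235 and RS06240. They were picked after their values were seen, as the only rows with at least 10 CPM in 17 of the 18 wild-type libraries and at most 5 counts in 17 of the 18 knock-out libraries. Their summed level was 152 ± 30.9 CPM (SD, n = 17) in those wild-type libraries and 0.0396 ± 0.0322 CPM (SD, n = 17) in those knock-out libraries. The library labelled wild type LD16:8 1 cycle replicate 2 had 4 counts in the 3 rows (0.0569 CPM). The library labelled knock-out LD16:8 1 cycle replicate 2 had 11021 counts (168 CPM). By mean correlation of log2 CPM with the other libraries of each group, the library labelled knock-out LD8:16 1 cycle replicate 2, whose code lies between theirs, was also closer to another group (0.957) than to its own (0.922). Among the libraries outside the codes 14 to 17, 15 of 23 of 4 or 8 cycles and 6 of 9 of 1 cycle were closest to their own group. All 3 were kept under their labels in the values below, so every difference that involves 1 cycle of LD16:8, and the genotype difference averaged over all 6 regimes, rests in part on libraries whose genotype label these rows go against. Differences that involve 1 cycle of LD8:16 in the knock-out rest in part on the 3rd library. Since all libraries share 1 fit, the other comparisons depend on the 3 as well. Without the 2 libraries that go against their genotype label, wild-type photoperiod calls at 8 cycles rose from 678 to 910.

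**Figure D1:**
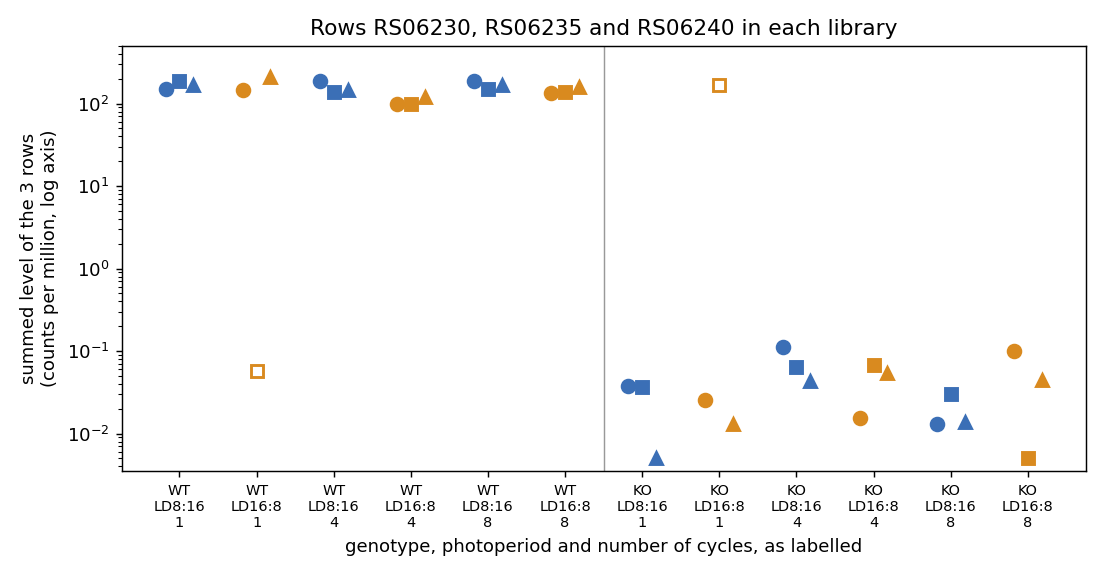
Summed level of rows RS06230, RS06235 and RS06240 in each of the 36 libraries (CPM, log axis), by labelled genotype, photoperiod and number of cycles. Blue is LD8:16, orange LD16:8, marker shape the replicate number; open markers are the 2 libraries that go against their genotype label, and libraries with 0 counts are drawn at the lower edge.

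The comparison of photoperiods in wild type asks how the transcriptome of cells with an intact clock differs between short and long days. After 8 cycles, 678 of 2617 tested rows (25.9%) differed, 289 higher and 389 lower in LD8:16. Of these, 100 were higher and 166 lower by at least 2-fold. Row RS01880 was at 1451 ± 85.8 CPM (SD, n = 3) in LD8:16 and 269 ± 16.1 CPM (SD, n = 3) in LD16:8, a log2 difference of 2.43 (SE 0.71, adjusted p = 0.0133). Row RS13555 was at 563 ± 214 and 70.5 ± 16.5 CPM (SD, n = 3), a difference of 3.00 (SE 1.00, adjusted p = 0.0281). Row RS07870 was at 43.95 ± 2.74 CPM (SD, n = 3) in LD8:16 and 1274 ± 517 CPM (SD, n = 3) in LD16:8, a difference of -4.86 (SE 1.17, adjusted p = 0.0031). Row RS08200 was at 21.96 ± 7.12 and 558 ± 138 CPM (SD, n = 3), a difference of -4.67 (SE 1.28, adjusted p = 0.00867). RS13555 lost its call (highest adjusted p 0.0954) when any of 4 of the 6 libraries was left out. With the 6 libraries fitted alone 1251 rows were called, and without the 3 doubted libraries 1027, of which 525 were higher and 502 lower, so the majority direction was not stable.

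After 4 cycles, 534 rows (20.4%) differed in wild type, 228 higher and 306 lower in LD8:16, with 117 and 105 of them by at least 2-fold. Row RS12960 was at 72.6 ± 23.7 CPM (SD, n = 3) in LD8:16 and 4.49 ± 3.20 CPM (SD, n = 3) in LD16:8, a difference of 4.02 (SE 0.81, adjusted p = 0.0017). Row RS01880, also higher after 8 cycles, was at 1833 ± 1007 and 207 ± 56.5 CPM (SD, n = 3), a difference of 3.15 (SE 0.74, adjusted p = 0.00434). Row RS12585 was at 134 ± 95 CPM (SD, n = 3) in LD8:16 and 1391 ± 455 CPM (SD, n = 3) in LD16:8, a difference of -3.37 (SE 0.98, adjusted p = 0.0175). Row RS08605 was at 37.3 ± 5.71 and 234 ± 55.0 CPM (SD, n = 3), a difference of -2.65 (SE 0.51, adjusted p = 0.00124). The count fell to 240 and 298 without LD8:16 replicate 1 or 3, and to 328 and 341 without LD16:8 replicate 2 or 3. It rose to 639 without LD8:16 replicate 2, whose code, 17, follows those of the 3 doubted libraries. The median SD of log2 CPM within the LD8:16 group was 0.24, and 0.14 without that library. The count rose to 928 without the 3 doubted libraries, to 989 without the codes 14 to 17 and to 1038 without the 12 libraries of 1 cycle. The majority direction turned to 303 higher and 224 lower with no count filter, to 271 and 254 with rna and assembled rows kept and to 450 and 341 without the 2 libraries that go against their genotype label, and RS12585 lost its call (highest adjusted p 0.0941) under 2 of 18 alternatives.

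The wild-type differences at 4 and at 8 cycles, which share no library but share each row's dispersion estimate, went largely the same way. Of the 534 rows called at 4 cycles, 510 had the same sign at 8 cycles (95.5%). Called at both were 108 rows higher in LD8:16, where 25.2 would be by chance, and 231 lower, where 45.5 would be; 1 row was called in opposite directions. Across the 2138 rows with a mean of at least 10 CPM the differences had a Spearman correlation of 0.73, given as a description since rows are not independent replicates.

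After 1 cycle, 111 rows were called in wild type, 57 higher and 54 lower in LD8:16. The 1-cycle groups varied more within themselves than the later ones: the median SD of log2 CPM within a group was 0.29 in LD8:16 and 0.385 in LD16:8 at 1 cycle, against 0.12 to 0.24 in the groups of 4 and 8 cycles. Without the library labelled LD16:8 replicate 2, which goes against its genotype label, the LD16:8 value was 0.152, within the range of the later groups. LD8:16 replicate 1 was closer by mean correlation of log2 CPM to LD16:8 replicates 1 and 3 (0.944) than to the rest of its own group (0.930). LD8:16 replicate 3 was closest to wild type LD16:8 at 8 cycles (0.941, against 0.935 for its own group). Across rows the difference at 1 cycle had a Spearman correlation of -0.26 with that at 4 cycles and -0.07 with that at 8 cycles. The count was 36, 49, 195 and 345 without LD8:16 replicate 2, LD8:16 replicate 3, LD8:16 replicate 1 and the library labelled LD16:8 replicate 2, and 436 without the 2 libraries that go against their genotype label. It was 0 with the 6 libraries fitted alone and 1 with the series of library codes as a covariate (all 3 LD8:16 libraries lie in the last series), and exchanging the photoperiods of 2 libraries of each group called 806 rows.

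The same comparison in the knock-out asks whether photoperiod differences occur without the clock genes. After 8 cycles, 315 rows (12%) differed, 156 higher and 159 lower in LD8:16, with 26 and 39 by at least 2-fold. Row RS12840 was at 2033 ± 320 CPM (SD, n = 3) in LD8:16 and 604 ± 196 CPM (SD, n = 3) in LD16:8, a difference of 1.75 (SE 0.34, adjusted p = 0.00193); in wild type it was at 3017 ± 493 and 3442 ± 70 CPM (SD, n = 3). Row RS04645 was at 81.6 ± 6.89 and 25.1 ± 4.97 CPM (SD, n = 3), a difference of 1.70 (SE 0.31, adjusted p = 0.00106). The 2 rows named above as lower in wild type at 8 cycles were called lower here as well. RS08200 was at 78.0 ± 63.6 CPM (SD, n = 3) in LD8:16 and 1026 ± 113 CPM (SD, n = 3) in LD16:8, a difference of -3.72 (SE 1.22, adjusted p = 0.0465), and RS07870 at 62.9 ± 22.5 and 725 ± 183 CPM (SD, n = 3), a difference of -3.53 (SE 1.10, adjusted p = 0.0352). The count was between 139 and 199 when any of the 6 libraries was left out, and RS08200 and RS07870 then lost their calls each time (highest adjusted p 0.168 and 0.136). It was 522 without the 2 libraries that go against their genotype label, 839 without the 1-cycle libraries and 906 with the 6 libraries fitted alone.

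After 4 cycles, 10 rows were called in the knock-out (3 higher and 7 lower in LD8:16), of 202 with an unadjusted p below 0.05. Row RS00225 was at 69.2 ± 19.9 CPM (SD, n = 3) in LD8:16 and 11.1 ± 3.81 CPM (SD, n = 3) in LD16:8, a difference of 2.64 (SE 0.53, adjusted p = 0.0219). Row RS13940 was at 18.7 ± 5.99 and 60.7 ± 2.52 CPM (SD, n = 3), a difference of -1.70 (SE 0.26, adjusted p = 0.00113). DESeq2 called 33 rows, and the count was 1 to 5 when any of the 6 libraries was left out, 27 without the 2 libraries that go against their genotype label and 135 without the 1-cycle libraries. RS00225 lost its call (highest adjusted p 0.102) under 5 of 18 alternatives.

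After 1 cycle, only row RS02620 was called in the knock-out, at 313 ± 100 CPM (SD, n = 3) in LD8:16 and 145 ± 5.23 CPM (SD, n = 3) in LD16:8 (log2 difference 1.114, SE 0.21, adjusted p = 0.0348). An unadjusted p below 0.05 was found for 653 rows, and DESeq2 called 222. Leaving out LD8:16 replicate 2 gave 750 calls, LD16:8 replicate 3 gave 333, LD16:8 replicate 1 gave 3, and LD8:16 replicate 1 or 3 gave 0. RS02620 lost its call (highest adjusted p 0.556) under 8 of 17 alternatives, among them the replicate number as a block and the 6 libraries fitted alone, and the count was 55 without the 2 libraries that go against their genotype label.

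The 8-cycle differences of wild type and knock-out share no library but share each row's dispersion estimate. They had the same sign in 639 of the 678 rows called in wild type. Called in both genotypes were 96 rows higher in LD8:16, where 17.2 would be by chance, and 130 lower, where 23.6 would be, with 2 rows called in opposite directions. Called in wild type alone were 450 rows, in the knock-out alone 87 and in neither 1852. These counts do not test a difference between the genotypes. Across 2138 rows the 2 differences had a Spearman correlation of 0.72; at 4 cycles the corresponding value was 0.19.

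**Figure D2:**
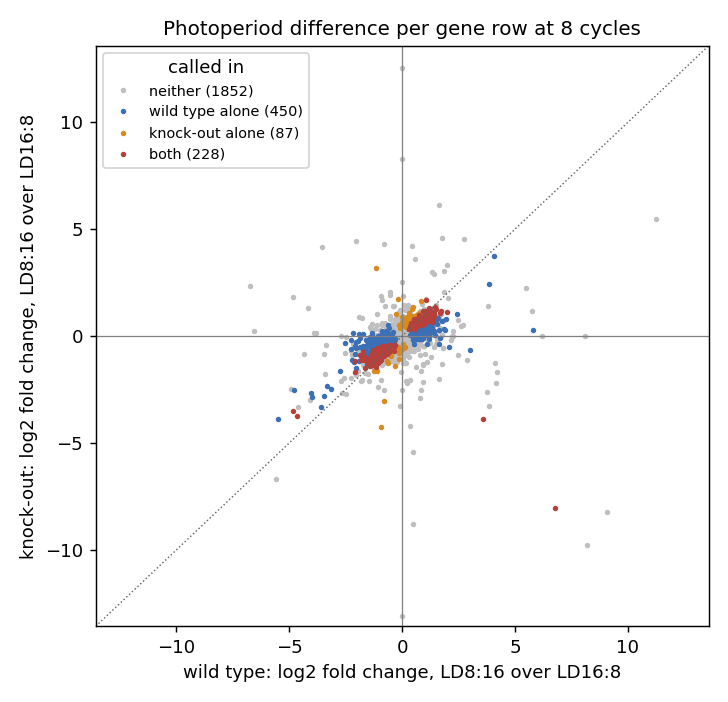
Log2 difference LD8:16 minus LD16:8 after 8 cycles of each of the 2617 tested gene rows. Wild type is on the horizontal and knock-out on the vertical axis, with 3 libraries in each group. Colours mark rows called in both genotypes, in wild type alone, in the knock-out alone or in neither.

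The test of genotype by photoperiod asks in which rows the photoperiod difference depends on the genotype. After 8 cycles no row was called: 0 by edgeR's quasi-likelihood test, of 200 with an unadjusted p below 0.05, and 14 by DESeq2. In simulated data the same comparison recovered 35% of 2-fold and 84% of 4-fold changes. Those data gave a row the same dispersion in every library, so they do not carry the smaller spread of the 8-cycle groups. The count was 14 without the 2 libraries that go against their genotype label, 160 without the 1-cycle libraries and 388 with the 12 libraries of 8 cycles fitted alone. Leaving out 1 library gave 0 to 2.

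After 4 cycles, 52 rows were called, 24 with a higher and 28 with a lower photoperiod difference in the knock-out. The split moved with the scaling, to 11 and 28 with DESeq2 size factors and 11 and 27 with rna and assembled rows kept. Row RS08605 was at 125 ± 30.2 CPM (SD, n = 3) in LD8:16 and 113 ± 17.6 CPM (SD, n = 3) in LD16:8 in the knock-out, against 37.3 ± 5.71 and 234 ± 55.0 CPM (SD, n = 3) in wild type (difference of differences 2.80, SE 0.69, adjusted p = 0.0354). Row RS13195 was at 25.6 ± 6.55 and 34.7 ± 4.96 CPM (SD, n = 3) in the knock-out, against 55.3 ± 27.1 and 8.94 ± 2.80 CPM (SD, n = 3) in wild type (-3.07, SE 0.57, adjusted p = 0.0253). The count was 0 to 144 when any of the 12 libraries was left out, 139 by DESeq2, 0 with the series of library codes as a covariate, 228 without the 2 libraries that go against their genotype label and 589 without the 1-cycle libraries. RS08605 lost its call under 12 of 24 alternatives and RS13195 under 5 of 24 (highest adjusted p 0.114 and 0.0953).

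After 1 cycle, 134 rows were called, 86 higher and 48 lower. Both libraries that go against their genotype label are in this comparison, in the LD16:8 groups of the 2 genotypes. Without them 52 rows were called, without the 3 doubted libraries 227, and with the 12 libraries of 1 cycle fitted alone 0. Leaving out any of 11 of the 12 libraries moved the count by over 1.5 times, to between 0 and 453.

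The rows called in wild type at 4 cycles were then followed as 1 score, the mean log2 CPM of the 228 higher rows minus that of the 306 lower rows. At 8 cycles, in libraries not used to choose the rows, wild type scored 0.29 ± 0.04 (SD, n = 3) in LD8:16 and -1.36 ± 0.10 (SD, n = 3) in LD16:8, a difference of 1.65 (SE 0.06). The knock-out scored 0.17 ± 0.02 and -0.56 ± 0.04 (SD, n = 3), a difference of 0.74 (SE 0.03). The groups did not overlap in either genotype (exact p = 0.1 each, the smallest that 3 against 3 libraries allow). The difference in the knock-out minus that in wild type was -0.92; when genotypes were regrouped within each photoperiod, which tests for no genotype difference in either photoperiod, its permutation p was 0.005, the smallest that 400 regroupings allow. The rows were chosen for a difference in wild type, which favours a larger wild-type value. Rows chosen in the knock-out at 8 cycles differed by 1.59 (SE 0.06) in wild type and 1.67 (SE 0.08) in the knock-out at 8 cycles, the latter on the libraries they were chosen on, and at 4 cycles by 0.93 and 0.22 (permutation p = 0.11). Rows chosen in wild type at 8 cycles differed at 4 cycles by 1.33 and 0.25 (permutation p = 0.065). At 4 cycles the knock-out differed by 0.26 (SE 0.09; exact p = 0.1). At 1 cycle the differences were -0.39 (SE 0.52; exact p = 0.5) in wild type and -0.69 (SE 0.48; exact p = 0.2) in the knock-out.

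**Figure D3:**
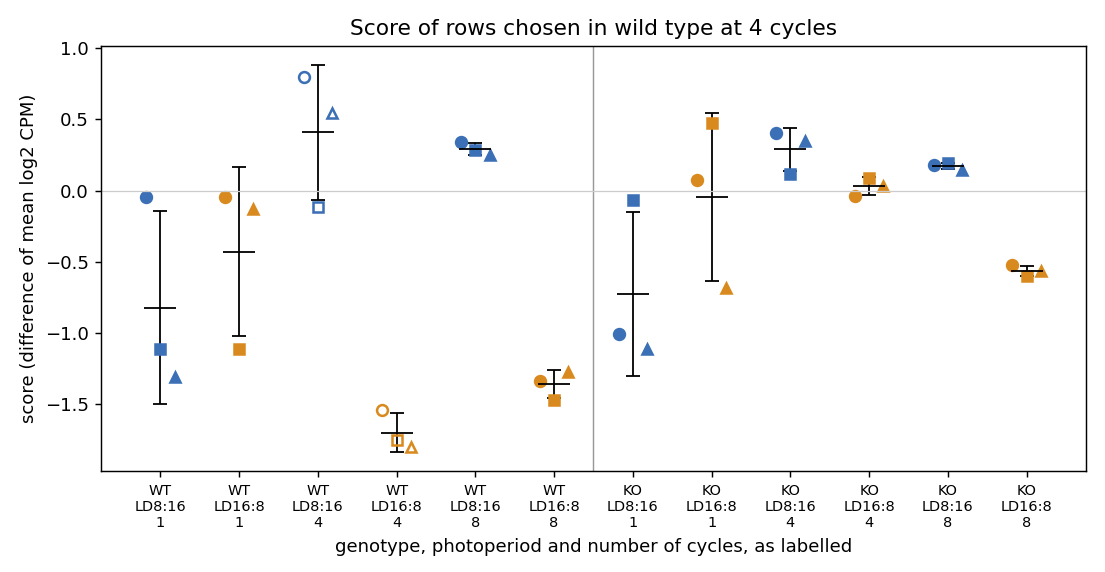
Score of the rows called between photoperiods in wild type at 4 cycles (mean log2 CPM of the higher rows minus that of the lower rows) in each library, by genotype, cycles and photoperiod. Blue is LD8:16 and orange LD16:8, marker shape is the replicate number, bars are mean ± SD (n = 3), and open markers are the libraries the rows were chosen on.

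The comparison of 8 with 1 cycle asks how the transcriptome differed between numbers of cycles. The constant light beforehand or a move to new plates may differ between these groups too. In wild type 392 rows differed in LD8:16 (172 higher and 220 lower after 8 cycles) and 363 in LD16:8 (186 higher and 177 lower). In the knock-out 350 differed in LD8:16 (112 higher and 238 lower) and 84 in LD16:8 (34 higher and 50 lower). Between 8 and 4 cycles 0 rows were called in wild type LD8:16, wild type LD16:8 and knock-out LD8:16 (148, 211 and 72 with an unadjusted p below 0.05; 4, 13 and 1 by DESeq2), and 103 in knock-out LD16:8 (55 higher and 48 lower at 8 cycles); without the libraries of 1 cycle these counts were 33, 174, 0 and 627, and without the 3 doubted libraries 3, 46, 0 and 482. The counts of 8 against 1 cycle fell to 233, 6, 1 and 0 when only the groups compared were fitted (wild type LD8:16 and LD16:8, knock-out LD8:16 and LD16:8), and without the 2 libraries that go against their genotype label they were 687, 491, 680 and 216. With the series of library codes as a covariate the count was 17 in wild type LD8:16, whose 1-cycle libraries all lie in the last series and whose 8-cycle libraries do not, and 42 in knock-out LD16:8. The majority direction turned in wild type LD16:8 to 152 higher and 207 lower with DESeq2 size factors and 199 and 297 with the DESeq2 test. In knock-out LD8:16 it turned to 596 and 559 without the 3 doubted libraries. For 8 against 4 cycles in knock-out LD16:8 it turned to 49 and 58 with DESeq2 size factors and 53 and 62 with no count filter. It was 210 and 272 there without the 3 doubted libraries, and 303 and 324 without the libraries of 1 cycle. Leaving out 1 library gave 121 to 727, 176 to 400, 0 to 840 and 13 to 138.

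The test of cycles by photoperiod asks in which rows the photoperiod difference changed from 1 to 8 cycles. In wild type 484 rows were called (214 higher and 270 lower at 8 cycles), and in the knock-out 366 (162 higher and 204 lower). From 4 to 8 cycles the counts were 1 and 18, with 242 and 379 without the libraries of 1 cycle, 90 and 221 without the 3 doubted libraries, and 2 and 3 with the series of library codes as a covariate. Without the 2 libraries that go against their genotype label the counts were 828 and 449, and with only the groups compared fitted they were 186 and 0; with the code series they were 264 and 217. Leaving out 1 library gave 258 to 729 in wild type and 86 to 751 in the knock-out.

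The comparison of genotypes asks what the knock-out changes on average over the 6 combinations of photoperiod and cycles. A call can rest on some of the 6 and need not hold in each. It called 1162 rows (44.4%), 557 higher and 605 lower in the knock-out. Most of these differences were small: the median size among called rows was 0.43 in log2 units, and 34 rows were higher and 64 lower by at least 2-fold. Row RS10135 was at 17126 ± 4744 CPM in the knock-out and 2442 ± 1895 CPM in wild type (SD, n = 18), a difference of 2.88 (SE 0.23, adjusted p = 3.33e-10). Row RS01090 was at 22.2 ± 27.4 and 4.54 ± 15.8 CPM (SD, n = 18); it had 0 counts in all 3 libraries of a wild-type group, so no fold is given. Row RS04315 was at 125 ± 512 CPM in the knock-out and 794 ± 543 CPM in wild type (SD, n = 18), a difference of -5.97 (SE 0.64, adjusted p = 6.17e-08). Without the 2 libraries that go against their genotype label RS04315 was at 4.63 ± 1.13 and 840 ± 522 CPM (SD, n = 17). Row RS12585, also lower in LD8:16 in wild type at 4 cycles, was at 31.1 ± 33.8 and 545 ± 599 CPM (SD, n = 18), a difference of -3.81 (SE 0.41, adjusted p = 6.17e-08). RS01090 lost its call (highest adjusted p 0.0661) under 1 of 46 alternatives, and the majority direction turned to 614 higher and 564 lower with no count filter, to 595 and 588 with rna and assembled rows kept and to 751 and 661 without the 2 libraries that go against their genotype label.

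Within single regimes the genotypes differed in 409, 204 and 152 rows after 1, 4 and 8 cycles of LD8:16, and in 14, 780 and 379 rows after 1, 4 and 8 cycles of LD16:8. The comparison with 14 calls, LD16:8 at 1 cycle, holds both libraries that go against their genotype label, and without them 465 rows were called. The 409 calls fell to 67 with the series of library codes as a covariate and rose to 636 without those 2 libraries and to 874 without the 3 doubted ones, and without the libraries of 1 cycle the counts at 4 and 8 cycles were 737 and 667 in LD8:16; in LD16:8 they were 647 higher and 571 lower at 4 cycles, and 858 in all at 8 cycles. Across 2138 rows the genotype differences at 4 and 8 cycles, averaged over photoperiods and sharing no library, had a Spearman correlation of 0.83, and 805 of the 831 rows called at 4 cycles had the same sign at 8 cycles.

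**Figure D4:**
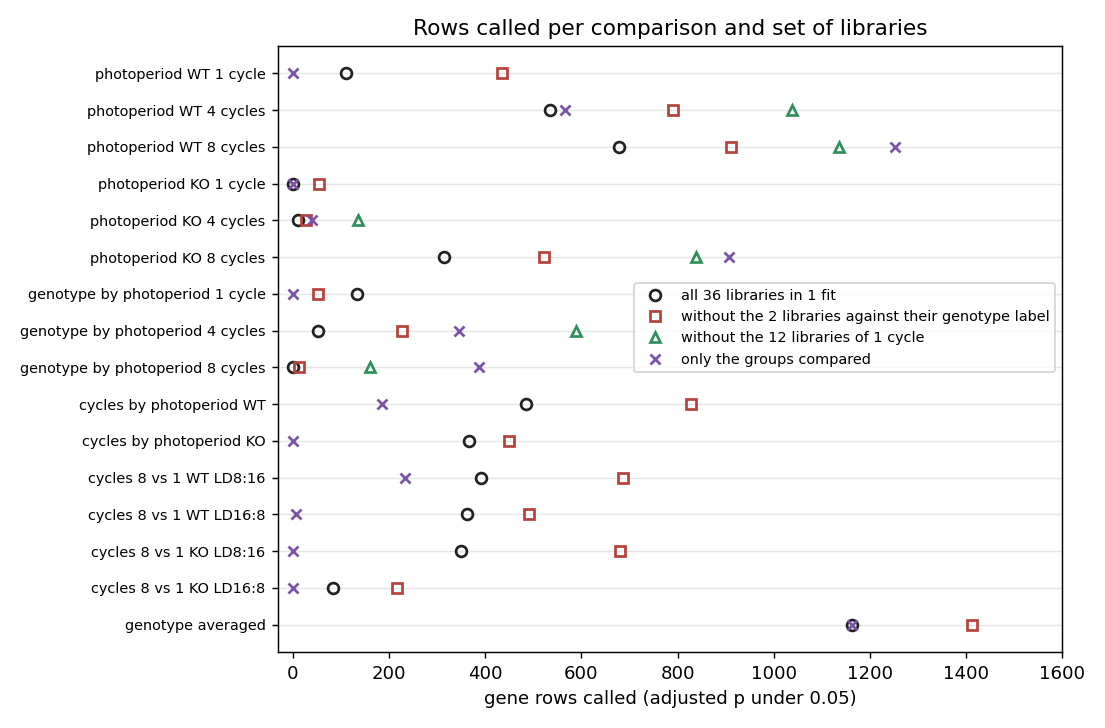
Gene rows called (adjusted p below 0.05) in each of the 16 comparisons. Circles are all 36 libraries in 1 fit, squares the fit without the 2 libraries that go against their genotype label, triangles the fit without the 12 libraries of 1 cycle, and crosses the fit of only the groups compared.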

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

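The contrasts, the DESeq2 test, the code series as covariate, the fit with rna and assembled rows kept and the cycles by photoperiod contrast from 4 to 8 cycles were planned; the other tests in this part were chosen after the results were seen.

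Flagged because the photoperiod difference itself differed between genotypes: 134 rows at 1 cycle and 52 at 4 cycles. Regrouping the libraries gave at least 134 calls in 9 of 50 splits (highest 663) and at least 52 in 5 of 50 splits (highest 496), and these splits cannot judge either count: a split that exchanges genotypes mostly in a single photoperiod turns the contrast toward the genotype difference itself. At 8 cycles 0 rows were called, and each of the 50 splits had at least as many (highest 94); the splits with 496 and 94 calls exchanged all 6 libraries of LD16:8 and 2 of LD8:16. A score of rows chosen in wild type at 4 cycles differed between genotypes at 8 cycles by -0.92 (permutation p = 0.005), and by -0.79 (permutation p = 0.005) when the rows were chosen without the libraries coded 14 to 17. That test is of no genotype difference in either photoperiod, and choosing rows in wild type favours wild type. Rows chosen in wild type at 8 cycles gave -1.08 at 4 cycles (permutation p = 0.065) and rows chosen in the knock-out at 8 cycles gave -0.71 (permutation p = 0.11); at 8 cycles the latter differed by 1.59 in wild type and 1.67 in the knock-out, where they were chosen.

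Flagged because the photoperiod difference changed from 1 to 8 cycles: 484 rows in wild type (1 of 50 splits reached it, the real one, highest other 292) and 366 in the knock-out (1 of 50, highest other 124). These splits cannot judge the counts either. A split that exchanges cycles mostly in a single photoperiod turns the contrast toward the difference between cycles, and exchanged groups mix unlike libraries.

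Flagged because rows outside the tested set were called when kept in: of the 55 rna rows, 9, 3 and 7 in wild type between photoperiods at 1, 4 and 8 cycles, 1 in the knock-out at 8 cycles, 8 for genotype by photoperiod at 1 cycle, 4 and 4 for cycles by photoperiod in wild type and knock-out, 4, 2 and 4 for 8 against 1 cycle in wild type LD8:16, wild type LD16:8 and knock-out LD8:16, and 14 between genotypes (4 higher and 10 lower in the knock-out). Of the 14 assembled rows, 2 were called in wild type between photoperiods at 4 cycles, 1 for cycles by photoperiod in the knock-out, 1 and 2 for 8 against 1 cycle in wild type LD8:16 and knock-out LD8:16, and 4 between genotypes. The IDs do not show which of these rows depend on the ribosomal RNA depletion.

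The library labelled wild type LD16:8 1 cycle replicate 2 (code 14) and the library labelled knock-out LD16:8 1 cycle replicate 2 (code 16) go against their genotype label in 3 rows. An exchange of these 2 labels alone is not in line with the data: the library coded 14 correlated less with the label of code 16 than with that of code 15, by a mean of -0.0531. Mixed cells are not in line with its counts either, which allow at most 0.0958% of wild-type RNA, a limit for counting error only that takes those rows at their mean level in wild type. A shift of the labels of the codes 14 to 17 by 1 place is consistent with the data: it ranked 1 of 24 orders of the 4 labels by mean correlation with other libraries of each label (0.958, against 0.917 as labelled and 0.933 with the exchange). The codes 14 to 16 were closer to the label of the next code, and 17 to that of code 14, with margins from 0.00387 for code 17, which decides little, to 0.0815, while 15 of 23 other libraries of 4 or 8 cycles and 6 of 9 of 1 cycle were closest to their own label; correlation cannot tell a label error from cultures that behaved differently, and no library was relabelled.

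The knock-out differed between photoperiods at 8 cycles in 315 rows, yet for genotype by photoperiod 0 rows were called by edgeR (200 with an unadjusted p below 0.05; DESeq2 called 14). Had the 6 libraries with disagreeing labels really been kept in LD16:8, no difference between those groups would be predicted, and the score differed by 0.74 in the knock-out, so that explanation is not in line with it. Hours after lights on, as the whole cause, predict the same difference at 4 and 8 cycles, whereas 18 rows differed between them (3 with the code series as covariate, 379 without the libraries of 1 cycle), and the knock-out score differed by 0.26 (SE 0.09) and 0.74 (SE 0.03) for rows chosen in wild type at 4 cycles and by 0.25 (SE 0.11) and 1.09 (SE 0.05) for rows chosen in wild type at 8 cycles (permutation p of the change 0.085 and 0.05). In these values the knock-out difference was larger at 8 than at 4 cycles. This test cannot decide on the hours, because constant light beforehand or a move to new plates may also differ between 4 and 8 cycles. The hours stay open as a part or as the whole cause. The absence of calls for genotype by photoperiod may come from the spread of the 1-cycle libraries in the shared estimate, since 160 rows were called without those libraries.

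The photoperiod difference at 1 cycle ran opposite to that in wild type at 4 cycles across rows (Spearman correlation -0.26 in wild type and -0.52 in the knock-out). The groups overlapped, however, in the score of the called rows (knock-out -0.69, exact p = 0.2). With the knock-out's own difference at 4 cycles, its 1-cycle difference had a correlation of 0.07, and 0.11 without the codes 14 to 17. The knock-out had only 10 calls at 4 cycles, so these correlations cannot show whether its difference reversed from 1 to 4 cycles. Without the codes 14 to 17, 203 rows were called in opposite directions in the knock-out at 1 and 8 cycles. Called higher in both were 44 rows and lower in both 59, where 56.2 and 56.1 would be by chance (Spearman correlation -0.18). In the knock-out at 1 cycle each series of library codes held 1 library of each photoperiod, by the labels. A shift of equal size within a series would cancel in that difference if the labels hold. The labels of the codes 15 and 16, the pair of 1 series, are doubted, so this balance cannot decide on the code series there. Within the other 2 series the correlation of the knock-out difference with wild type at 4 cycles was -0.33 and -0.54. Each came from 1 library against 1, which has no spread. In wild type all LD8:16 libraries of 1 cycle lie in the last series, so there the code series stays open. Mislabelling among codes 14 to 17 is not a likely whole cause in the knock-out. Its correlation with wild type at 4 cycles stayed at -0.44 without them, with 2 libraries in each group. Exchanged photoperiod labels at 1 cycle could not be told apart by the lower correlation with the 8-cycle difference, -0.18. The constant light given beforehand was not tested and stays open.

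For comparisons with 10 possible splits the splits are too few to judge the counts, and only the values are given. Photoperiod calls in wild type were 111 at 1 cycle (2 of 10 splits reached it, highest other 806), 534 at 4 cycles (1 of 10, 4) and 678 at 8 cycles (1 of 10, 0); in the knock-out they were 1 (3 of 10, 801), 10 (1 of 10, 1) and 315 (1 of 10, 0). For 8 against 1 cycle the highest other counts were 2 and 69 in wild type LD8:16 and LD16:8, and 82 and 2 in the knock-out, each with 1 of 10 splits reaching the real count. For the averaged genotype difference (1162) it was 1 of 50, highest other 109. The splits with 806 and 801 calls point to structure among the 1-cycle libraries: the 1st exchanged the codes 2 and 26 with 40 and 41, the 2nd the code 15 with 28. The 1st thus put code 38, labelled wild type LD8:16, with the codes 2 and 26, labelled wild type LD16:8. By mean correlation code 38 was closer to these (0.944) than to 40 and 41 (0.930). Its score for rows chosen in wild type at 4 cycles was -0.047. The codes 2 and 26 scored -0.045 and -0.127, and 40 and 41 scored -1.11 and -1.31.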

How the results depend on the processing

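The settings in this paragraph were planned before the data were examined. DESeq2 size factors, no count filter, and rna and assembled rows kept moved none of the 16 counts of calls by over 1.5 times. The split of calls did move. The majority direction turned for photoperiod in wild type at 1 cycle from 57 higher and 54 lower to 51 and 55 with DESeq2 size factors and 53 and 58 with no filter, at 4 cycles from 228 and 306 to 303 and 224 with no filter and 271 and 254 with rna and assembled rows kept, and in the knock-out at 8 cycles from 156 and 159 to 161 and 157 with DESeq2 size factors and 165 and 152 with no filter. It turned for 8 against 1 cycle in wild type LD16:8 from 186 and 177 to 152 and 207 with DESeq2 size factors and 160 and 200 with no filter, and for the averaged genotype difference from 557 and 605 to 614 and 564 with no filter and 595 and 588 with rna and assembled rows kept. With the DESeq2 test it turned for photoperiod in wild type at 1 cycle (95 and 136), cycles by photoperiod in wild type (296 and 284) and 8 against 1 cycle in wild type LD16:8 (199 and 297), with the replicate number as a block for genotype by photoperiod at 4 cycles (26 and 23), with the code series for the knock-out at 8 cycles (120 and 115) and without the 6 libraries with disagreeing labels for 8 against 1 cycle in knock-out LD16:8 (9 and 4). For genotype by photoperiod at 4 cycles 46.2% were higher as reported, 28.2% with DESeq2 size factors and 28.9% with rna and assembled rows kept, and for 8 against 1 cycle in knock-out LD16:8 40.5% and 28.7% with DESeq2 size factors. With the DESeq2 test, photoperiod calls were 231 in wild type at 1 cycle (41.1% higher, against 51.4%) and 222 and 33 in the knock-out at 1 and 4 cycles; genotype by photoperiod gave 219, 139 (33.1% higher) and 14 at 1, 4 and 8 cycles, and 8 against 1 cycle 209 in knock-out LD16:8. With the code series as covariate, photoperiod gave 1 in wild type and 0 in the knock-out at 1 cycle, genotype by photoperiod 6, 0 and 1, cycles by photoperiod 264 in wild type and 217 in the knock-out, and 8 against 1 cycle 17 in wild type LD8:16 and 42 in knock-out LD16:8. With the replicate number as a block, the 1 call of the knock-out at 1 cycle became 0, and the block moved none of the other 15 counts; of the comparisons added later it moved the genotype difference at 1 cycle of LD16:8 from 14 to 1. The numbers do not pair the libraries: in no comparison were all 3 correlations of same-numbered libraries over 0.1. Without the 6 libraries with disagreeing labels, photoperiod gave 40 in wild type at 1 cycle and 0 and 5 in the knock-out at 1 and 4 cycles, genotype by photoperiod 27 and 0 at 1 and 4 cycles, and 8 against 1 cycle 13 in knock-out LD16:8; comparisons that need those libraries have no value. With only the groups compared, photoperiod gave 0 and 1251 in wild type at 1 and 8 cycles and 0, 41 and 906 in the knock-out at 1, 4 and 8 cycles, genotype by photoperiod 0, 345 and 388, cycles by photoperiod 186 and 0, and 8 against 1 cycle 233, 6, 1 and 0 (wild type LD8:16 and LD16:8, knock-out LD8:16 and LD16:8). With 8 against 4 in place of 8 against 1 cycle, cycles by photoperiod gave 1 in wild type and 18 in the knock-out. The cause was not tested for any of these. The gene list tests were planned and not run, since 0 IDs matched.

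The settings in this paragraph were chosen after the data were seen, and each fits fewer libraries. Values are in the order photoperiod in wild type at 1, 4 and 8 cycles, photoperiod in the knock-out at 1, 4 and 8 cycles, genotype by photoperiod at 1, 4 and 8 cycles, cycles by photoperiod in wild type and knock-out, and 8 against 1 cycle in wild type LD8:16 and LD16:8 and knock-out LD8:16 and LD16:8. Without the 2 libraries that go against their genotype label: 436, 791, 910, 55, 27, 522, 52, 228, 14, 828, 449, 687, 491, 680 and 216. Without the codes 14 to 16: 598, 928, 1027, 759, 67, 672, 227, 384, 42, 980, 871, 835, 626, 1155 and 330. Without the codes 14 to 17: 632, 989, 1065, 819, 86, 723, 272, 546, 89, 1029, 937, 896, 672, 1200 and 381. Averaged genotype calls were 1412, 1458 and 1478 under these 3. Without the 12 libraries of 1 cycle, photoperiod gave 1038 and 1135 in wild type at 4 and 8 cycles and 135 and 839 in the knock-out, and genotype by photoperiod 589 and 160. The majority direction (higher and lower) turned in these cases. Photoperiod in wild type at 1 cycle: 185 and 251 without the 2 libraries that go against their genotype label, 279 and 319 without the codes 14 to 16, 289 and 343 without 14 to 17. At 4 cycles: 450 and 341, 526 and 402, 542 and 447, and 563 and 475 without the libraries of 1 cycle. At 8 cycles: 464 and 446, 525 and 502, 543 and 522, and 572 and 563. Photoperiod in the knock-out at 8 cycles: 280 and 242, 351 and 321, 380 and 343, under the same 3 settings as at 1 cycle in wild type. At 1 cycle in the knock-out: 362 and 397 without 14 to 16, 389 and 430 without 14 to 17. Cycles by photoperiod: 516 and 513 in wild type without 14 to 17, and 454 and 417, then 490 and 447, in the knock-out without 14 to 16 and 14 to 17. For 8 against 1 cycle: 233 and 258, 306 and 320, 328 and 344 in wild type LD16:8 under the 3 settings, and 596 and 559, then 613 and 587, in knock-out LD8:16 without 14 to 16 and 14 to 17. Averaged genotype: 751 and 661, 749 and 709, 775 and 703 under the 3 settings. The cause was not tested beyond the fewer libraries.

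Counts of the comparisons added after the data were seen moved as follows. For 8 against 4 cycles in wild type LD8:16 and LD16:8 and knock-out LD8:16 and LD16:8, as reported 0, 0, 0 and 103: DESeq2 4, 13, 1 and 211, without the 6 libraries with disagreeing labels 0 and 31 in LD16:8 of wild type and knock-out, without the codes 14 to 16 3, 46, 0 and 482, without the libraries of 1 cycle 33, 174, 0 and 627. For cycles by photoperiod from 4 to 8 cycles in wild type and knock-out, chosen before the data were examined, as reported 1 and 18: DESeq2 21 and 74, code series 2 and 3, without the codes 14 to 16 90 and 221, without the libraries of 1 cycle 242 and 379. For the genotype difference after 1, 4 and 8 cycles of LD8:16 and then of LD16:8, as reported 409, 204, 152, 14, 780 and 379: DESeq2 491, 320, 250, 95, 859 and 446, code series 67, 113, 112, 0, 749 and 318, without the 6 libraries with disagreeing labels 297 and 113 at 1 and 4 cycles of LD8:16 and 0, 675 and 296 in LD16:8, without the 2 libraries that go against their genotype label 636, 476, 420, 465, 1018 and 574, without the codes 14 to 16 874, 570, 539, 589, 1126 and 725, and without the libraries of 1 cycle 737 and 667 at 4 and 8 cycles of LD8:16, 647 higher and 571 lower at 4 cycles of LD16:8 and 858 at 8 cycles of LD16:8. The cause was not tested.

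Leaving out each library in turn, a planned setting, moved 85 of 156 counts, and for a group compared it leaves 2 libraries. The lowest and highest counts were, for photoperiod in wild type, 36 to 345, 240 to 639 and 479 to 537 at 1, 4 and 8 cycles; in the knock-out 0 to 750, 1 to 5 and 139 to 199; for genotype by photoperiod 0 to 453, 0 to 144 and 0 to 2; for cycles by photoperiod 258 to 729 in wild type and 86 to 751 in the knock-out; for 8 against 1 cycle 121 to 727, 176 to 400, 0 to 840 and 13 to 138 (wild type LD8:16 and LD16:8, knock-out LD8:16 and LD16:8); and for the averaged genotype difference 1114 to 1310. Of 558 values of named rows with a library left out, 382 kept their direction and side of the threshold, 175 kept direction only and 1 turned: row RS04315, at 7.31 for cycles by photoperiod in the knock-out, was at -0.098 without knock-out LD16:8 1 cycle replicate 2, at 7.94 without knock-out LD16:8 1 cycle replicate 3 (its highest) and at -0.061 without the 2 libraries that go against their genotype label. With 3 libraries in each group and 35% of simulated 2-fold changes recovered for genotype by photoperiod at 8 cycles, a row without a call is not a row without a difference. Rows below 0.0277 to 0.0539 CPM cannot be told from 0 at these depths.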

Other observations

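The comparisons in this part were chosen after the results were seen. Rows with neighbouring ID numbers moved together. Between each tested row and the next in ID order, the log2 differences had a Spearman correlation of 0.27 and 0.29 between photoperiods in wild type at 4 and 8 cycles, 0.28 in the knock-out at 8 cycles and 0.23 between genotypes, where 1000 permutations of the row order gave at most 0.0714. Runs of at least 4 neighbouring rows called in the same direction numbered 10 in wild type at 4 cycles (at most 5 in the permutations), 15 at 8 cycles (at most 7), 4 in the knock-out at 8 cycles (at most 2) and 28 between genotypes (at most 20). The files give no positions, so ID order stands in for gene order.

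Genotype differences were set against wild-type photoperiod differences in libraries not shared by the 2 comparisons. The genotype difference at 4 cycles and the wild-type photoperiod difference at 8 cycles had a Spearman correlation of 0.43 across 2138 rows. Called lower in both were 200 rows, where 66.9 would be by chance. Called higher in both were 102, where 42.1 would be, and 24 rows were called in opposite directions. The genotype difference at 8 cycles and the wild-type photoperiod difference at 4 cycles had a correlation of 0.17. There 96 rows were called lower in both, where 39.4 would be by chance. Only 27 were called higher in both, where 25.2 would be, and 27 in opposite directions. Without the codes 14 to 17 these counts were 159, 144 and 164, so the overlap did not hold for all rows. Rows are not independent replicates, the chance values leave out the shared dispersion estimate, and no p is given.

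Without the libraries coded 14 to 17, the median SD of log2 CPM within a group was 0.15 in wild type LD16:8 at 1 cycle, 0.13 and 0.20 in knock-out LD8:16 and LD16:8 at 1 cycle, and 0.14 in wild type LD8:16 at 4 cycles, with 2 libraries left in each. It was 0.29 in wild type LD8:16 at 1 cycle, whose 3 libraries carry the codes 38, 40 and 41, all in the last series of codes. The wild-type and knock-out photoperiod differences at 1 cycle had a Spearman correlation of 0.05 with all libraries, 0.51 without the 2 libraries that go against their genotype label and 0.53 without the codes 14 to 17.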
